A study of Bos taurus with 12 samples.

How the data were processed

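Total RNA of elongated bovine conceptuses and of the fibroblasts used as nuclear donors was amplified, labelled with biotin and hybridized to Affymetrix bovine genome arrays, per the labels' protocols. There were 12 arrays in 4 groups of 3: AI, IVP and SCNT conceptuses of day 16, and fibroblasts (FB). The deposited table holds log2 signals of 24128 probe sets per array. GCRMA and limma were named as tools, per the submitters' processing notes, while their versions and whether all arrays were normalized together are not given in the sources used here. The values ran from 2.42 to 13.66, and 36.8% lay within 0.01 of the lowest, which sets a floor below which levels cannot be told apart. No column of the table was left unused, apart from 112 control probe sets, whose exclusion left 24016.

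Gene symbols came from the array annotation: 13292 probe sets had 1 symbol, 86 had several and 10638 had none. Of these probe sets 13263 matched a gene ID of the ARS-UCD2.0 gene table, used only for names, which changed 0 symbols. The symbols stand for 9155 genes. No genome was used and no coordinates are given.

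The deposited log2 values were used without further normalization. Probe sets above log2 4 on at least 3 arrays were tested, 6892 in the fit of the 9 conceptus arrays and 8164 in the fit of all 12 arrays. Fibroblast arrays were left out of the conceptus fit because cultured cells may vary less than conceptuses. Linear models with 1 coefficient per group and moderated t-tests were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 6 and 8 residual degrees of freedom. SCNT was compared with AI, IVP with AI, SCNT with IVP, and each conceptus group with FB. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the probe sets of each comparison, and an adjusted p under 0.05 was called a change. Intervals are 95%, and errors are SD of the arrays unless SE is written. The median standard error of 0.16 sets the precision.

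Where a group's mean lay below log2 4, its arrays below log2 4 were set to 4 before its fold was computed, so that the fold is a lower bound. Of 32 gene lists with 1237 names, the 24 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, using the brightest probe set of each of 4349 genes, and again with an estimated correlation. Adjustment was over the lists of a comparison. Genes of a list were called over all probe sets and, beside that, adjusted over the list alone. The lists cover trophoblast transcription factors and keratins, secreted trophoblast proteins, hypoblast and yolk sac, fibroblast markers, MHC class I, prostaglandins, steroids, cholesterol, fatty acid synthesis and oxidation, glycolysis, oxidative phosphorylation, amino acid transport, imprinting, chromatin, unfolded protein response, heat shock, oxidative stress, hypoxia, cell cycle, apoptosis and p53, adhesion, WNT, TGF-beta and FGF signalling, and ribosomal proteins. For donor-cell genes, the 500 probe sets highest and the 500 lowest in FB against the conceptus group outside the comparison were tested with camera, adjusted over 4 tests.

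Genes named for a conceptus comparison were those with exactly 1 symbol, an adjusted p under 0.05 and no overlap between the groups' arrays, namely the 10 largest rises and the 10 largest falls, plus up to 4 changed members of each list. Comparisons with FB named 5 in each direction and list members. A fixed set of genes of interest was given whether changed or not. Groups, tests, lists, the naming rule and the other settings to be tried were chosen before the data were examined. These settings were other filters, thresholds, normalizations, floors, variance models, sets of arrays in the fit, list sizes, a replicate block and the omission of each array in turn. Spike-in, GAPDH and XIST covariates, the omission of the 3 arrays with high spike-in signal and a different order of filtering for the donor-cell lists were added after the data had been seen. Other splits of the arrays into groups of equal size were counted.

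The shared AI arrays were handled by simulating unchanged groups against the same arrays 100 times. The procedure was tested on simulated data for SCNT against AI, with 200 of 6892 probe sets changed in 10 runs. It recovered 8.80% of them at 1.5-fold, 91.4% at 2-fold and 99.8% at 4-fold, and 5.88%, 5.97% and 4.77% of the calls were false. Of 20 simulated lists of 15 genes moved by 0.50 log2 units, 20 had an unadjusted camera p under 0.05, and of 20 unmoved lists 1 had. Genes were simulated independently of each other and without adjustment over lists. These runs therefore cannot tell how reliable a list call is where the genes of a list vary together.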

Results

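Gene expression was measured in bovine conceptuses recovered on day 16 of gestation, when the embryo and its trophoblast form an elongated filament before attachment to the uterus. Blastocysts of 3 origins had been transferred to recipient cows on day 7, and conceptuses of similar length were collected. AI conceptuses came from embryos produced in vivo after artificial insemination, IVP conceptuses from oocytes fertilized and cultured in vitro, and SCNT conceptuses from somatic cell nuclear transfer, in which the nucleus of a body cell replaces that of the oocyte. The fibroblasts that served as nuclear donors (FB) formed the fourth group, and each group had 3 arrays. The labels do not say whether the arrays of a group came from separate animals or pools, so p-values measure the spread between arrays labelled as replicates, which may be partly technical.

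Between 6359 and 6643 of 24016 probe sets lay above log2 4 on each array, or 26.5% to 27.7%. Conceptus arrays of one group correlated at 0.978 or above (Pearson's r across the 8164 probe sets tested over all arrays, which are not independent replicates). The correlation between IVP and SCNT arrays was 0.974 to 0.985, that between AI and IVP arrays 0.945 to 0.968, and that between AI and SCNT arrays 0.942 to 0.951. Conceptus and fibroblast arrays were far apart, with r from 0.512 to 0.533 for AI. The number of arrays limits the precision of each value, and the median standard error of a difference between conceptus groups was 0.16 on the log2 scale.

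The comparison of SCNT with AI conceptuses asked how expression after nuclear transfer differed from that after insemination. HSD17B1, whose enzyme converts estrone to estradiol, was 27.9-fold higher in SCNT conceptuses (95% interval 17.6 to 44.3), at 10.25 ± 0.75 against 5.45 ± 0.17 log2 units (mean ± SD, n = 3 each, adjusted p = 4.55e-06). The fatty acid transporter gene SLC27A6 was at least 7.71-fold higher and cyclin D2 (CCND2) at least 4.93-fold higher. Where a group's mean lay below log2 4, its level is only a bound, so its arrays below log2 4 were set to 4 and the fold was written as "at least". TKDP2, a Kunitz-domain protein secreted by ruminant trophoblast, was at least 91.1-fold lower in SCNT conceptuses (3.03 ± 0.28 against 10.51 ± 0.57, adjusted p = 2.77e-07). The tetraspanin gene TSPAN1 was 37.5-fold lower (16.0 to 87.9, adjusted p = 1.43e-04), and AHSG, the gene of the plasma protein fetuin-A, was 25.9-fold lower (11.9 to 56.3, adjusted p = 1.58e-04).

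Other large rises in SCNT conceptuses were those of NHERF1 (6.97-fold), the glutathione peroxidase gene GPX1 (6.94-fold), the acyltransferase gene MOGAT1 (6.09-fold), GPD1L (5.73-fold), DNASE1L3 (5.53-fold) and SSBP2 (at least 4.22-fold). IGHM was at least 10.7-fold higher, a call that ended without AI 1, AI 3, SCNT 1 or SCNT 2 (adjusted p up to 0.0621). Large falls included ITGB2, a leukocyte integrin subunit (20.2-fold), the GTPase gene RAC2 (17.8-fold), ALAS2 of heme synthesis (at least 6.98-fold), the calcium-binding protein gene S100G (at least 5.02-fold), the peptidase inhibitor gene SPINK4 (at least 5.67-fold) and C5H12orf75 (at least 4.20-fold). LOC404105 was 12.9-fold lower (2.33 to 71.5), a call that ended without any 1 of AI 1, AI 2, AI 3, SCNT 2 and SCNT 3. Over the omission of each array, kept calls included, its log2 difference ran from -4.71 to -2.88. Globin genes and the leukocyte gene PTPRC, examined after these results, stayed below log2 4 on every AI array, beside ITGB2, RAC2 and ALAS2.

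Over all 6892 probe sets tested, 1902 differed between SCNT and AI at an adjusted p under 0.05, 1117 higher and 785 lower in SCNT, which took in 805 and 481 named genes. Of these, 181 were at least 2-fold higher and 304 at least 2-fold lower. The arrays of the groups did not overlap for 1871 of the 1902, while over all tested probe sets 44.3% did not overlap and chance gives 10% for 3 against 3. The median difference of all probe sets was 0.08. Without SCNT 2 the count was 1190.

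**Figure D1:**
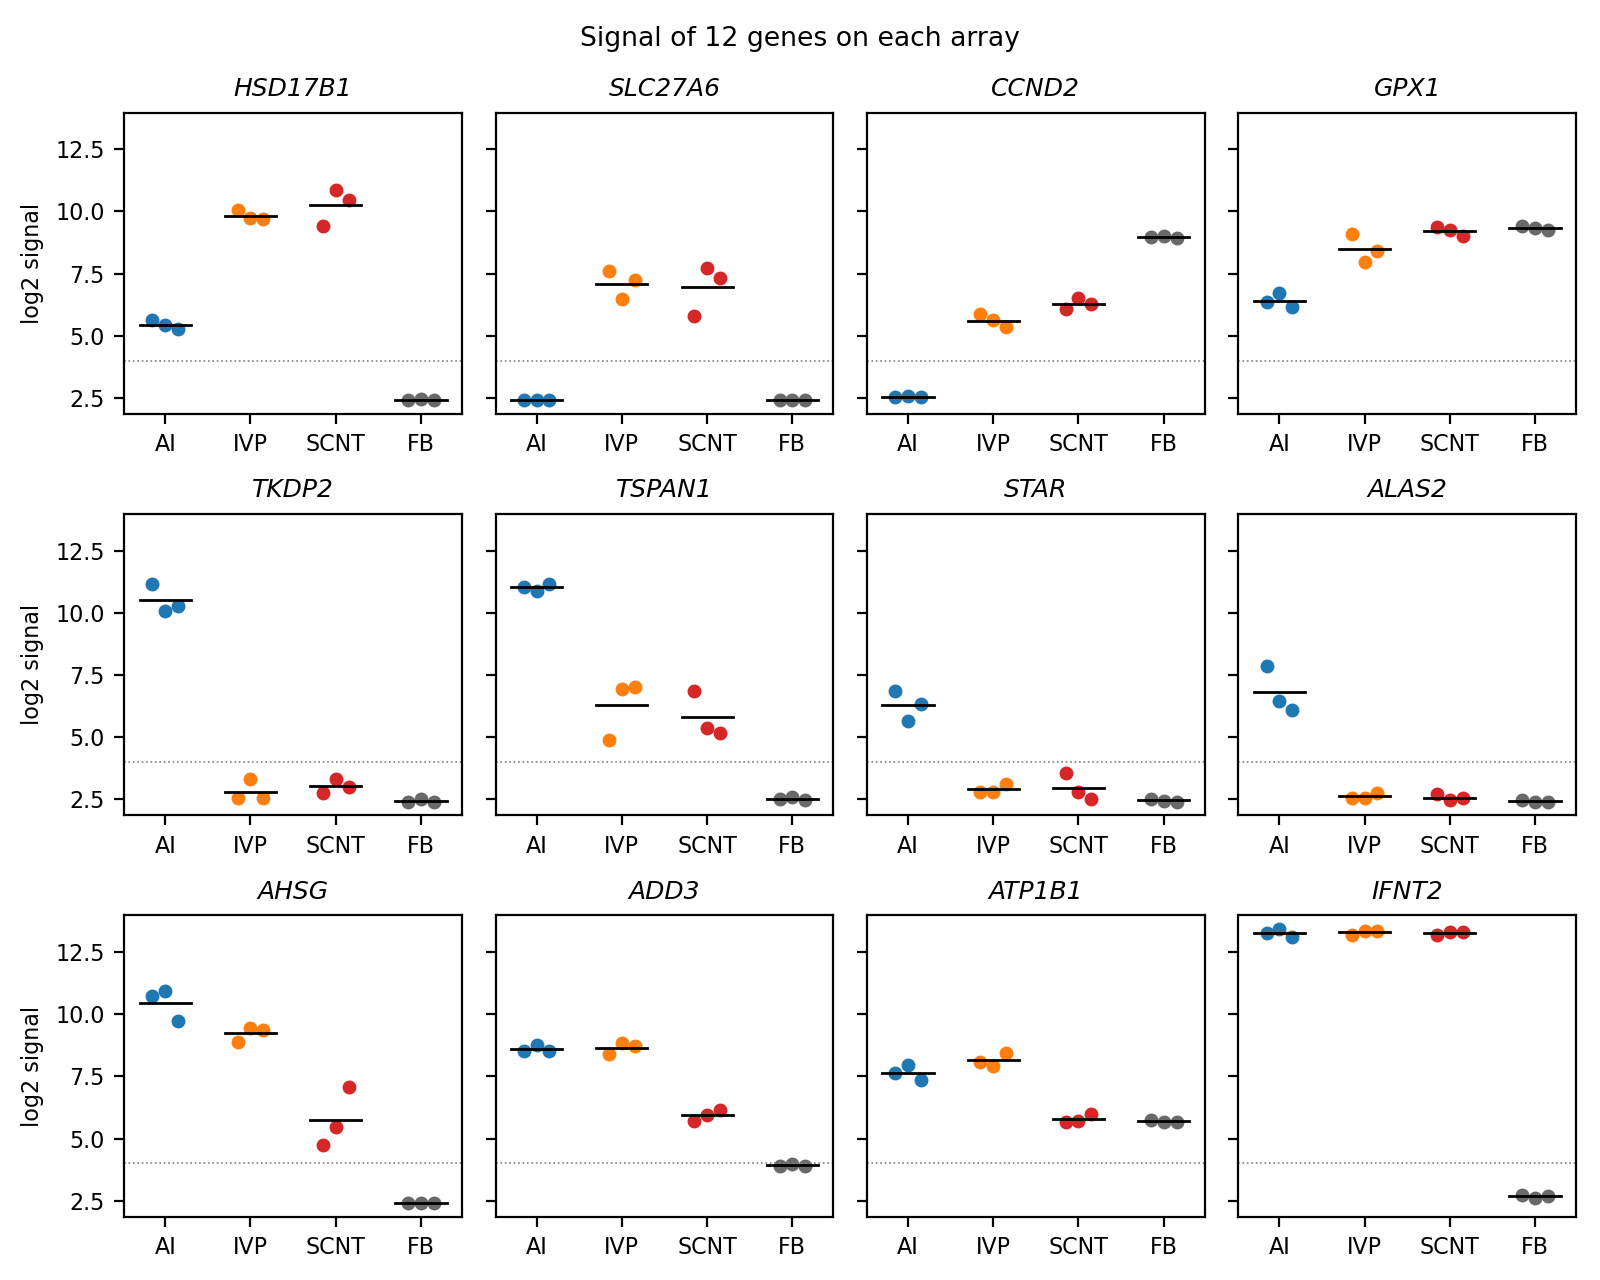
Log2 signal (y axis) of 12 genes on each of the 3 arrays of the AI, IVP, SCNT and FB groups (x axis), with the group mean as a bar and log2 4 as a dotted line. HSD17B1, SLC27A6, CCND2 and GPX1 lie lower on the AI arrays than on the IVP and SCNT arrays, TKDP2, TSPAN1, STAR and ALAS2 lie higher on the AI arrays, and AHSG, ADD3 and ATP1B1 are lowest in SCNT among the conceptuses.

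Genes of lipid and steroid metabolism moved in both directions in SCNT conceptuses. Of 18 genes of fatty acid synthesis, uptake and storage, 7 were higher and 1 lower (8 and 2 adjusted over the list alone, list adjusted p = 0.0979), with ACSL3 4.07-fold, FADS2 3.23-fold and SCD 2.62-fold higher. Among 11 steroid genes 2 rose and 2 fell, as also adjusted over the list alone (adjusted p = 0.875). Besides HSD17B1 these were the lipoprotein receptor gene SCARB1 (4.67-fold higher), STAR, which moves cholesterol into mitochondria (at least 4.89-fold lower), and TSPO (at least 5.22-fold lower). The cholesterol synthesis list was lower as a group (adjusted p = 0.0482, but adjusted p = 0.554 with an estimated correlation), with 4 of 16 genes lower and 12 not passing, 4 also adjusted over the list alone. Its members CYP51A1, EBP and HMGCS1 fell by 1.14, 0.97 and 0.73 on the log2 scale. Of 17 genes of fatty acid oxidation 2 were lower, also adjusted over the list alone (adjusted p = 0.0571), the larger fall being that of the carnitine carrier gene SLC25A20 (3.27-fold). Of 10 prostaglandin genes PTGES was at least 2.89-fold higher and RXRA 2.21-fold lower (1 and 3 adjusted over the list alone, adjusted p = 0.444). RXRA encodes a nuclear receptor.

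The 11 secreted trophoblast proteins shifted lower in SCNT conceptuses (adjusted p = 0.0482, adjusted p = 0.362 with an estimated correlation), with 1 higher, 3 lower and 7 not passing, the same counts adjusted over the list alone. PAG11, of the pregnancy-associated glycoproteins, rose 2.32-fold, and TKDP4 and the protease inhibitor gene TIMP2 fell 2.31-fold and 4.97-fold. PAG, TKDP and interferon tau genes are families of close relatives whose transcripts may bind each other's probes, so the member named is uncertain. Of 14 trophoblast transcription factors and keratins, 3 rose and 3 fell (3 and 4 adjusted over the list alone, adjusted p = 0.245), among them ASCL2 (3.03-fold higher), KRT18 (1.84-fold higher) and HAND1 (3.19-fold lower). Of 12 hypoblast and yolk-sac genes, 1 rose and 4 fell (3 and 5 adjusted over the list alone, adjusted p = 0.0793), with the retinol carrier gene RBP4 2.80-fold lower, the fibrinogen gene FGG at least 2.30-fold lower and APOM at least 2.22-fold lower. Of 9 imprinted genes 4 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.329), with the cell cycle inhibitor gene CDKN1C 3.20-fold, IGF2R 2.16-fold and SNURF 2.04-fold higher.

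The hypoxia list was lower in SCNT conceptuses (adjusted p = 0.0482, adjusted p = 0.554 with an estimated correlation), with 1 of 16 genes higher and 4 lower, the same counts adjusted over the list alone. NDRG1 fell 4.37-fold, MXI1 at least 2.75-fold and BNIP3L 2.21-fold, while VEGFA, an angiogenic growth factor gene, rose 2.22-fold. The apoptosis and p53 list was lower too (adjusted p = 0.0482, adjusted p = 0.362 with an estimated correlation). Of its 15 genes 1 rose and 4 fell, also adjusted over the list alone: the death receptor gene TNFRSF1A (at least 2.30-fold), the p53 targets CDKN1A (at least 1.71-fold) and TP53I3 (2.44-fold), and GADD45B (3.02-fold). Of 18 integrin and adhesion genes 1 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.0482, adjusted p = 0.362 with an estimated correlation), with the tight junction genes CLDN1 (at least 2.74-fold) and CLDN4 (1.80-fold) and the integrin gene ITGAV (2.28-fold) lower and CDH2 1.94-fold higher. Of 19 WNT, TGF-beta and FGF genes 2 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0482, adjusted p = 0.438 with an estimated correlation), including the receptor gene FGFR2 (4.08-fold lower) and ID2 (2.17-fold lower). In the camera test 0 of the 24 lists passed with an estimated correlation after adjustment and 3 had an unadjusted p under 0.05. All 6 list calls ended without AI 2, when 0 lists passed, and 3 lists passed without SCNT 1. They also ended with the spike or the XIST level as a covariate (adjusted p from 0.0641 to 0.0809). The apoptosis, cholesterol and WNT calls also ended without AI 3 and without SCNT 1, the adhesion call without SCNT 1 and the hypoxia call without SCNT 2, with adjusted p up to 0.0988.

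No other list passed in this comparison, with adjusted p from 0.0571 to 0.875 over 18 lists. Of 26 oxidative stress genes 9 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.111), with GPX1, TXNRD1 (3.11-fold) and the catalase gene CAT (2.15-fold) higher and GSTO1 at least 8.57-fold lower. Of 35 cell cycle genes 6 rose, also adjusted over the list alone (adjusted p = 0.0649), NDC80 and MCM6 by 0.59 and 0.53 on the log2 scale. Of 19 heat shock genes 7 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.373), with HSPA4 1.80-fold higher and HSPB1 2.19-fold lower. Among 19 genes of the unfolded protein response 4 rose, also adjusted over the list alone (adjusted p = 0.525). Among 10 amino acid transporters 2 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.0649), SLC7A5 by 1.93-fold upward and the peptide transporter gene SLC15A1 by 2.33-fold downward. Of 26 chromatin genes 2 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.875), with UHRF1 1.68-fold higher and KDM6A at least 1.82-fold lower. The 13 probe sets of EED went in both directions, so its change is uncertain. Of 18 glycolysis genes 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.397), with LDHB 1.57-fold higher and the aldolase gene ALDOC at least 1.95-fold lower. Of 70 oxidative phosphorylation genes 9 rose (3 adjusted over the list alone, adjusted p = 0.189), with UQCRQ and UQCRB higher by 0.79 and 0.59 on the log2 scale. Of 6 MHC class I genes 2 rose, also adjusted over the list alone (adjusted p = 0.875). Of 60 ribosomal protein genes 1 rose, with 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (adjusted p = 0.444). Of 7 fibroblast marker genes 1 rose, with 0 adjusted over the list alone and 1 higher and 2 lower at an unadjusted p under 0.05 (adjusted p = 0.444). For steroid, chromatin and ribosomal genes the list's median, mean and test did not share a sign relative to all genes.

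The comparison of IVP with AI conceptuses asked the same of culture and fertilization in vitro. SLC27A6 was at least 8.60-fold higher in IVP conceptuses (7.10 ± 0.59 against 2.42 ± 0.00, n = 3 each, adjusted p = 1.11e-04), HSD17B1 was 20.9-fold higher (13.2 to 33.1) and CCND2 at least 3.07-fold higher. CRIPTO, which encodes a co-receptor of NODAL, was at least 3.30-fold higher (adjusted p = 1.07e-05). TKDP2 was at least 91.1-fold lower (adjusted p = 2.67e-07), TSPAN1 27.0-fold lower (11.5 to 63.2) and the epithelial gene PLET1 at least 10.0-fold lower (adjusted p = 6.39e-05). Rises also included DNASE1L3 (6.26-fold), NHERF1 (2.32 on the log2 scale), GPD1L (4.34-fold), GPX1 (4.24-fold) and SCARB1 (4.19-fold). B2M, the light chain of MHC class I, was 5.32-fold higher (2.13 to 13.3), a call that ended without AI 1 or IVP 2. Over the omission of each array, kept calls included, its log2 difference lay between 1.70 and 3.06. The call of a brighter B2M probe set held whichever array was left out. All 3 probe sets of B2M passed, by 1.56 to 2.41 on the log2 scale, and all 3 also rose in SCNT against AI, by 1.25 to 2.02. Falls included LOC404105 (34.0-fold, 6.14 to 188), ITGB2 (14.0-fold), ALAS2 (at least 6.98-fold), SPINK4 (at least 5.67-fold), S100G (at least 5.02-fold), C5H12orf75 (at least 4.20-fold) and CD48, a surface protein gene of leukocytes (at least 3.78-fold).

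Of the 6892 probe sets, 1234 differed between IVP and AI, 580 higher and 654 lower in IVP, covering 429 and 387 named genes, and 118 and 253 of them were at least 2-fold higher and lower. The majority changed sides with other scalings, to 651 higher and 636 lower with quantile normalization and 650 higher and 625 lower with the arrays centred on their medians. The groups did not overlap for 1223 of these and for 37.4% of all tested probe sets, against 10% by chance. The count was 794 without AI 3, 798 without IVP 1, 814 without IVP 3 and 580 without the 3 arrays with the highest spike-in signal (AI 2, IVP 2 and IVP 3).

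Heat shock genes were higher in IVP conceptuses as a group (adjusted p = 0.0257, adjusted p = 0.713 with an estimated correlation). Of 19 genes 8 rose and 11 did not pass (10 higher and 1 lower adjusted over the list alone), led by the co-chaperone genes BAG3 (3.33-fold, adjusted p = 0.00256) and DNAJB1 (2.21-fold, adjusted p = 0.00805). HSPA1A rose by 0.84 and AHSA1 by 0.75 on the log2 scale, and both calls ended without IVP 1 or IVP 3, that of HSPA1A also without AI 1 or AI 2. Over the omission of each array, kept calls included, their log2 differences were 0.68 or more and 0.49 or more. Of the 5 probe sets of HSPA1A 2 passed, with differences from -0.08 to 0.84. The GAPDH signal gap between 3' and 5' probe sets, a sign of RNA quality, was 0.35 to 0.89 on the IVP arrays and 0.21 to 0.38 on the AI arrays. The list of fatty acid synthesis, uptake and storage was higher as well (adjusted p = 0.0315, adjusted p = 0.571 with an estimated correlation), with 8 of 18 genes higher and 1 lower (9 and 2 adjusted over the list alone). Besides SLC27A6, ACSL3 rose 3.22-fold and FADS2 3.08-fold, while the fatty acid-binding protein gene FABP5 fell 3.25-fold. Without AI 1 the fatty acid list did not pass, with adjusted p = 0.0804 and 1 list left, while 4 lists passed without AI 2, and adjusted p over all settings of both lists ranged from 0.00288 to 0.713. With an estimated correlation 0 lists passed and 1 had an unadjusted p under 0.05.

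The other 22 lists did not pass in IVP against AI, with adjusted p from 0.0551 to 0.996. Of 15 apoptosis and p53 genes 1 rose and 3 fell (1 and 5 adjusted over the list alone, adjusted p = 0.0551), with TP53I3 3.23-fold and CDKN1A at least 1.71-fold lower. Of 11 secreted trophoblast proteins 1 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.0723, or 0.0211 with the spike covariate), with PAG8 3.13-fold lower and PAG11 2.09-fold higher. Of 14 trophoblast transcription factors and keratins 2 rose and 2 fell (2 and 3 adjusted over the list alone, adjusted p = 0.302), namely ASCL2 (2.61-fold higher), KRT18 (1.73-fold higher), HAND1 (3.42-fold lower) and ELF3 (at least 2.48-fold lower), whose call ended without AI 1, AI 3 or any IVP array (adjusted p up to 0.0937). Of 18 adhesion genes 2 rose and 6 fell (2 and 7 adjusted over the list alone, adjusted p = 0.140), with CLDN1 at least 2.74-fold and ITGAV 2.06-fold lower. Of 19 WNT, TGF-beta and FGF genes 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.254), with BMP7 2.01-fold higher on 1 of its 2 probe sets and FGFR2 3.87-fold lower. Of 11 steroid genes 2 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.705), with STAR at least 4.89-fold and TSPO at least 5.22-fold lower. Of 12 hypoblast and yolk-sac genes 3 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.992). Of 16 hypoxia genes 3 rose and 1 fell (4 and 2 adjusted over the list alone, adjusted p = 0.937), with VEGFA 2.50-fold higher and MXI1 2.81-fold lower. Of 26 oxidative stress genes 5 rose and 2 fell (7 and 2 adjusted over the list alone, adjusted p = 0.155), with TXNRD1 2.32-fold higher and GSTO1 at least 6.02-fold lower. Of 9 imprinted genes 2 rose (3 adjusted over the list alone, adjusted p = 0.728), ASCL2 and IGF2R (2.02-fold).

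Single genes passed in the remaining lists of IVP against AI. Of 16 cholesterol genes 1 fell (adjusted p = 0.155), of 17 fatty acid oxidation genes 1 fell (SLC25A20, 3.18-fold, adjusted p = 0.302) and of 26 chromatin genes 2 fell (adjusted p = 0.937), each the same adjusted over the list alone. Of 18 glycolysis genes 2 rose and 2 fell (adjusted p = 0.996) and of 35 cell cycle genes 1 rose and 1 fell (adjusted p = 0.465), again the same adjusted over the list alone. Of 10 amino acid transporters 2 rose and 3 fell (2 and 4 adjusted over the list alone, adjusted p = 0.155). Of 10 prostaglandin genes 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.814), with PTGES at least 2.77-fold higher. Of 6 MHC class I genes 2 rose (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.871). Of 70 oxidative phosphorylation genes 7 rose, with 0 adjusted over the list alone and 16 higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 0.0610). Of 60 ribosomal protein genes 1 rose, with 0 adjusted over the list alone and 2 unadjusted (adjusted p = 0.155). In limma 0 of the 26 genes of the unfolded protein response and fibroblast lists passed, also adjusted over the list alone, and 6 had an unadjusted p under 0.05 (adjusted p = 0.679 and 0.949). For hypoblast, prostaglandin, glycolysis, imprinted and chromatin genes the median, mean and test did not share a sign.

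Changes against AI were largely common to both kinds of conceptus. HSD17B1, SLC27A6, CCND2, NHERF1, GPX1, DNASE1L3 and GPD1L were among the largest rises, and TKDP2, TSPAN1, ITGB2, ALAS2, S100G, SPINK4, C5H12orf75 and LOC404105 among the largest falls, in SCNT and in IVP conceptuses. In all, 995 probe sets changed the same way in both comparisons, 462 higher and 533 lower, and 0 changed in opposite directions. They made up 52.3% of the SCNT calls and 80.6% of the IVP calls. Independent lists of these sizes would share 94.0 higher and 74.5 lower probe sets. Unchanged groups simulated against the same AI arrays shared at most 1 (100 simulations), but groups without changes yield almost no calls. That count therefore cannot tell how many of the 995 the shared AI arrays add. The log2 differences correlated at 0.870 across probe sets, against 0.499 in the simulations, and their covariance was 0.311 against 0.0186. The simulations use the same AI arrays, so the simulated covariance is what their spread adds on average, which leaves 0.293. A difference common to the 3 AI arrays, technical or not, would enter both comparisons as well. It cannot be told apart here, since these arrays cannot be split into parts of at least 2.

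**Figure D2:**
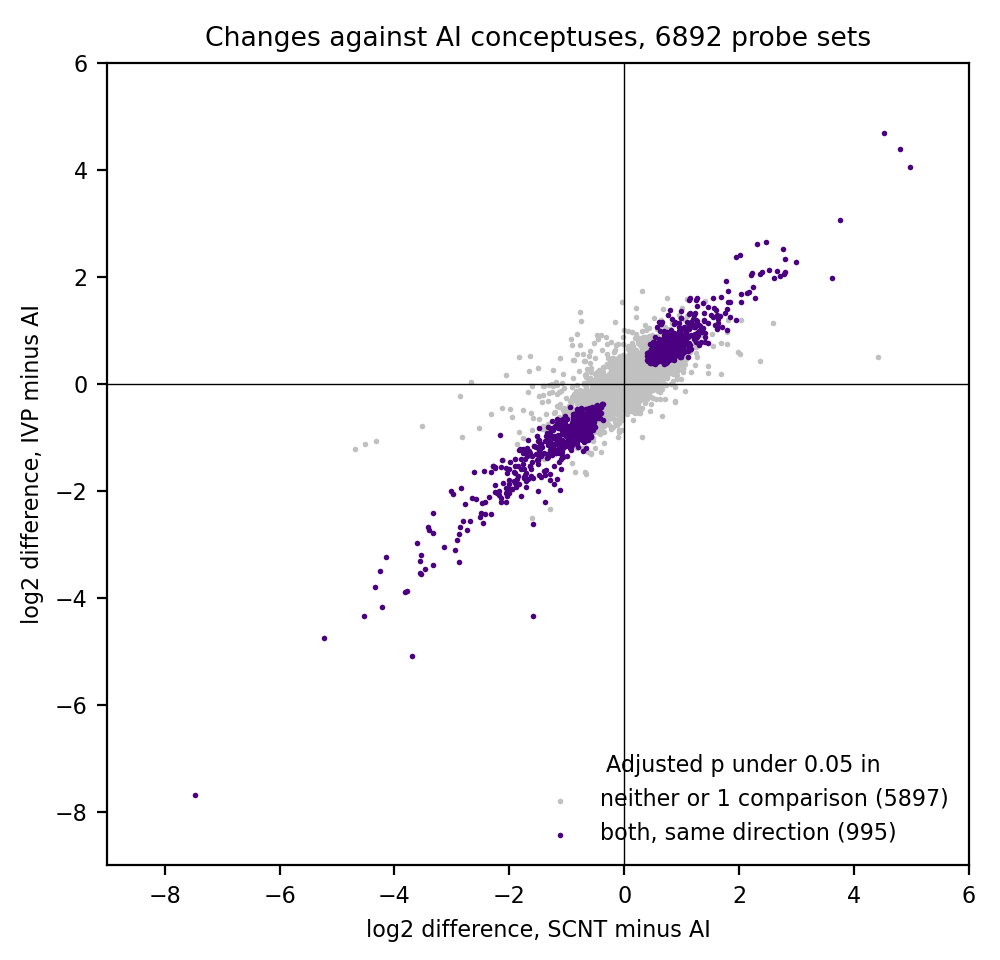
Log2 difference from AI of SCNT (x axis) and of IVP conceptuses (y axis), 1 point per probe set for the 6892 tested, with the 995 that passed in both comparisons in the same direction in dark colour. The points lie along the diagonal and 0 dark points lie in the quadrants of opposite direction.

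Few genes passed between SCNT and IVP conceptuses, both made outside the animal. ADD3, which encodes a protein of the membrane skeleton, was 6.49-fold lower in SCNT (5.06 to 8.34), at 5.94 ± 0.23 against 8.64 ± 0.23 log2 units (n = 3 each, adjusted p = 4.46e-05). ATP1B1, a subunit of the sodium pump, was 5.06-fold lower (3.79 to 6.76, adjusted p = 4.02e-04), and ZFAND2A at least 1.53-fold lower (adjusted p = 0.00122). PLET1 was at least 3.32-fold higher in SCNT than in IVP (5.73 ± 0.79 against 2.98 ± 0.39, adjusted p = 0.0105), with AI higher still at 7.33 ± 0.45. These 4 genes kept their calls whichever array was left out. The calls of MARK1 (at least 1.60-fold), PIGW (1.91-fold), TXNDC9 (1.87-fold), PLPP5 (at least 1.11-fold) and PPP1CC (1.58-fold), all higher in SCNT, ended without at least 5 of the 6 arrays left out in turn. PLET1, PLPP5 and PPP1CC passed on 1 of their 2 probe sets each.

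Of 6892 probe sets, 40 differed between SCNT and IVP, 16 higher and 24 lower in SCNT (6 and 15 named genes). In limma 876 had an unadjusted p under 0.05, where chance gives 345. The procedure recovered 8.80% of 1.5-fold changes simulated for SCNT against AI, so more and smaller differences than these 40 may exist. With the arrays centred on their medians the split was 10 higher and 25 lower. The groups did not overlap for all 40, and for 19.7% of all tested probe sets against 10% by chance. The count was 9 without SCNT 2, 15 without IVP 2, 18 without IVP 3, 20 without SCNT 3, 24 without SCNT 1 and 5 without the 3 arrays of highest spike-in signal. Spike signal parted the 2 groups, with hybridization spikes at 8.07 to 8.20 on the SCNT and 8.40 to 8.94 on the IVP arrays and poly-A spikes at 4.84 to 5.28 and 5.38 to 6.44. With the spike, GAPDH or XIST level as a covariate the count was 2, 8 or 7. The 40 differences then kept a median 0.896, 0.968 and 0.933 of their size, beside standard errors 1.32, 1.20 and 1.23 times as large.

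The hypoxia list was lower in SCNT than in IVP conceptuses (adjusted p = 7.31e-06, adjusted p = 0.537 with an estimated correlation), with 1 of 16 genes lower (3 adjusted over the list alone). That gene, NDRG1, was 3.20-fold lower (2.08 to 4.93, adjusted p = 0.0337), and without SCNT 1, SCNT 2, IVP 1, IVP 2 or IVP 3 it did not pass. Its log2 difference ran from -1.97 to -1.46 over the omission of each array, kept calls included. The hypoblast and yolk-sac list was lower too (adjusted p = 3.30e-04, adjusted p = 0.537 with an estimated correlation). With the spike covariate neither passed, as the hypoxia shift went from -0.46 to -0.30 (adjusted p = 0.0722) and the hypoblast list had adjusted p = 0.344, or 0.0663 with the XIST covariate. In limma 0 of its 12 genes passed, 1 higher and 2 lower passed when adjusted over the list alone, and 1 higher and 5 lower had an unadjusted p under 0.05. COL4A1, APOA2 and DAB2 are named here after their values were seen. The log2 differences of COL4A1, of basement membranes, and of DAB2 were -0.84 ± 0.25 and 0.44 ± 0.13 (± SE), and the lipoprotein gene APOA2 was at least 1.30-fold lower. Leaving out SCNT 1 gave 6 lists, and leaving out SCNT 2, SCNT 3 or IVP 1 gave 4. Adjusted p of the hypoxia and hypoblast lists ranged from 5.07e-09 to 0.537 over all settings, and 0 lists passed or had an unadjusted p under 0.05 with an estimated correlation.

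Of 19 heat shock genes 2 were lower in SCNT (5 adjusted over the list alone, adjusted p = 0.0502, or 4.80e-04 with the spike and 0.0248 with the XIST covariate). DNAJB1 and HSPA1A were 2.49-fold and 2.44-fold lower, calls that ended without SCNT 2, SCNT 3 or any IVP array. Over the omission of each array, kept calls included, the log2 difference of HSPA1A ran from -1.50 to -1.16. Only 1 of the 5 probe sets of HSPA1A passed, with differences from -1.38 to 0.07. Of 19 WNT, TGF-beta and FGF genes BMP7 alone was lower (2.02-fold, on 1 of its 2 probe sets), with 3 adjusted over the list alone (list adjusted p = 0.174). BMP7 did not pass without SCNT 1, SCNT 2, SCNT 3, IVP 2 or IVP 3. Its log2 difference ran from -1.20 to -0.90 over the omission of each array, kept calls included. In limma 0 of the 416 genes of the other 20 lists passed, with 5 adjusted over the list alone, 39 at an unadjusted p under 0.05 and adjusted p of the lists from 0.131 to 0.835. Those 20 were the lists of trophoblast transcription factors and keratins, secreted trophoblast proteins, fibroblast markers, MHC class I, prostaglandins, steroids, cholesterol, fatty acid synthesis, fatty acid oxidation, glycolysis, oxidative phosphorylation, amino acid transport, imprinting, chromatin, the unfolded protein response, oxidative stress, cell cycle, apoptosis, adhesion and ribosomal proteins. In the trophoblast transcription factor, prostaglandin, fatty acid synthesis and unfolded protein response lists the median, mean and test did not share a sign.

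**Figure D3:**
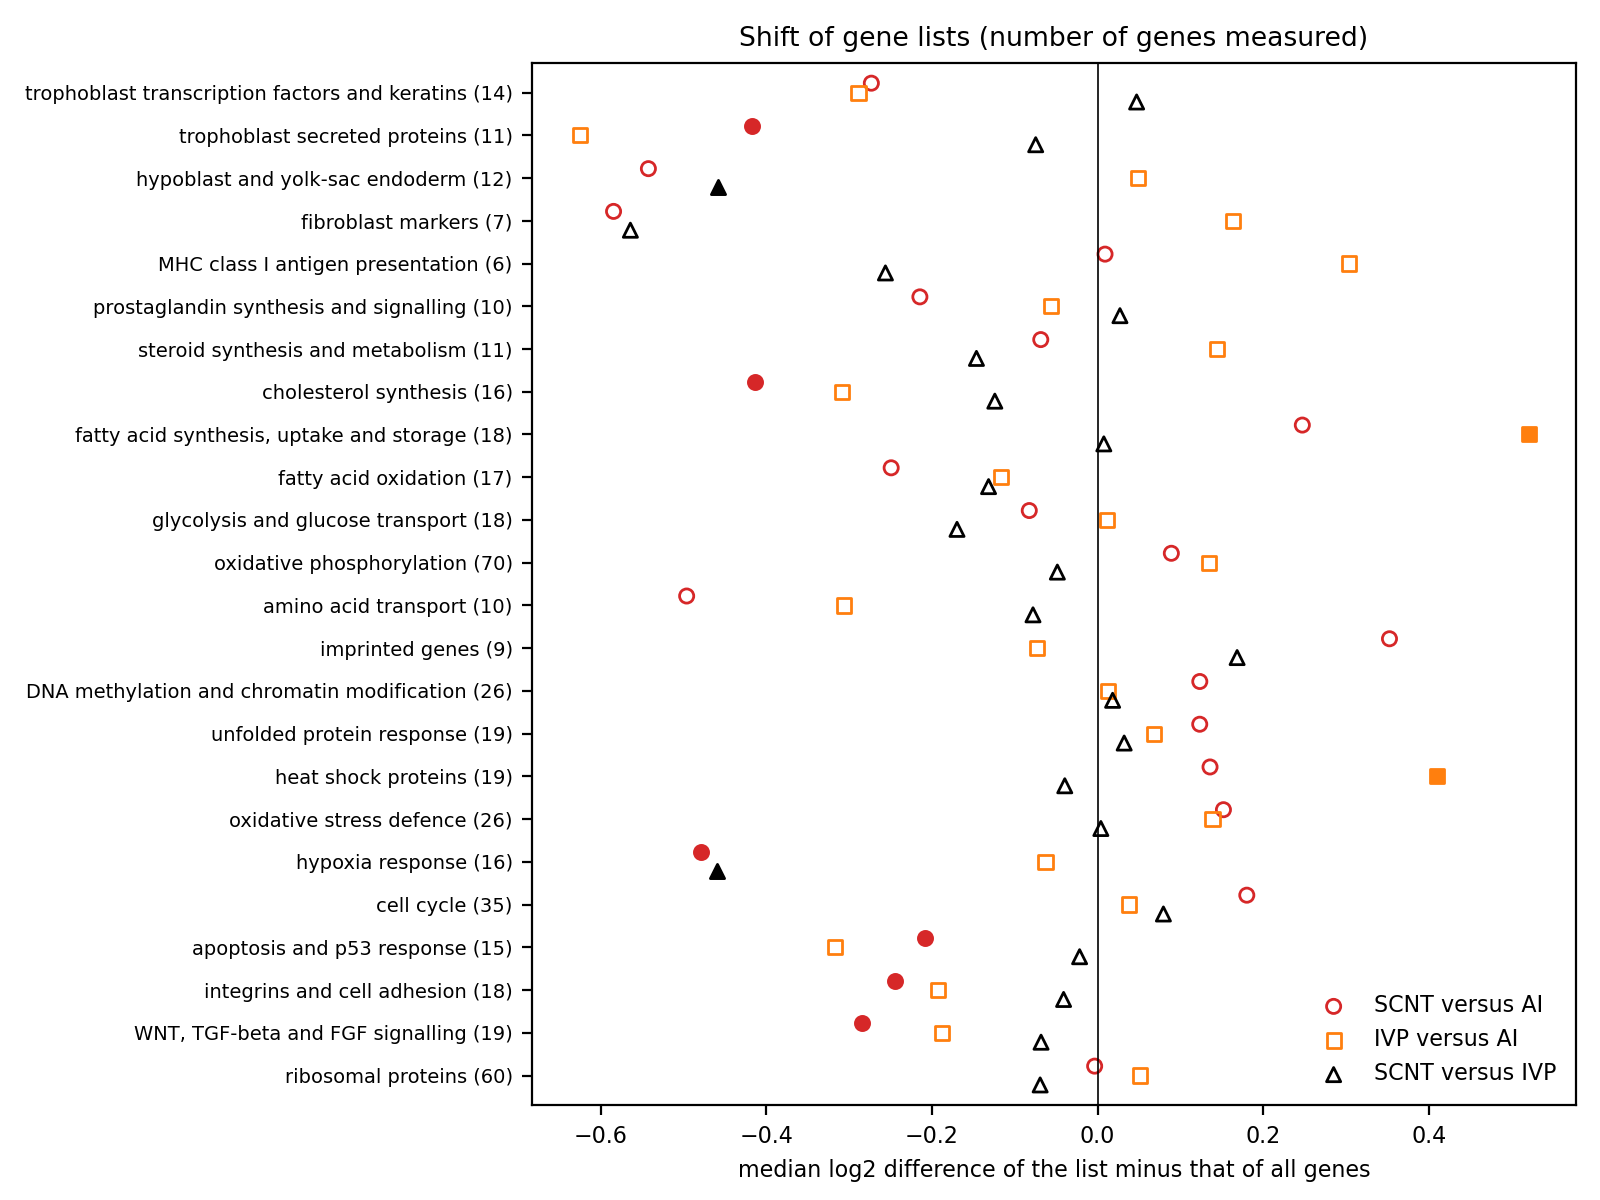
Median log2 difference of each of 24 gene lists minus that of all genes (x axis) in SCNT against AI (circles), IVP against AI (squares) and SCNT against IVP (triangles), with the number of genes measured behind each name. Filled symbols mark the 6, 2 and 2 lists with an adjusted p under 0.05 in the camera test.

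Donor fibroblasts were compared with SCNT conceptuses to ask whether genes typical of the donor cell stood higher after nuclear transfer. The 500 probe sets highest in fibroblasts relative to IVP conceptuses were lower in SCNT than in AI, with a median 0.25 below that of all probe sets (shift -0.25, adjusted p = 2.40e-05 over 4 tests, 62 higher and 114 lower). When the 500 were taken relative to AI conceptuses, the shift was -0.0020 and did not pass the camera test. Neither list answers the question for SCNT against AI, because IVP and SCNT conceptuses shared departures from AI (995 probe sets), so that choosing probe sets low in IVP by itself favours probe sets low in SCNT, and choosing those low in AI favours the opposite. The 500 probe sets lowest in fibroblasts shifted by -0.06 (adjusted p = 0.161, 94 higher and 103 lower), or by -0.41 when taken relative to AI. Against IVP conceptuses, SCNT conceptuses showed shifts of -0.07 for the fibroblast-high and -0.04 for the fibroblast-low probe sets (adjusted p = 0.00386 each, from lists relative to AI), with 2 higher and 1 lower, and 1 higher and 10 lower. The latter had p = 0.0780 with an estimated correlation, and without IVP 2 its shift was -0.02 and did not pass. The medians of the fibroblast-high and fibroblast-low probe sets were -0.01 and 0.02, against 0.06 for all probe sets. Both lists moved downward together, so these small shifts do not set donor-cell genes apart. Of the 40 probe sets that differed between SCNT and IVP, 34 also differed between AI and FB. SCNT differed from IVP in the direction in which FB differed from AI for 25 of them and in the other for 9, and in the former for 44.0% of all 5068 tested probe sets that differed between AI and FB. The 40 hold several probe sets of one gene and this share was not tested.

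Conceptuses of the 3 origins were also set against the fibroblasts. TKDP1, a trophoblast Kunitz-domain gene, was at least 784-fold, 749-fold and 722-fold higher in AI, IVP and SCNT conceptuses, and the interferon tau gene IFNT2 at least 610-fold, 626-fold and 615-fold higher (adjusted p of 1.24e-15 or below in the 6 tests). PAG2 was at least 412-fold, 419-fold and 382-fold higher, and the keratin gene KRT18 at least 298-fold, 515-fold and 549-fold higher. SSLP1 and KRT19 were at least 449-fold and 357-fold higher in AI conceptuses. Both were bright on the IVP and SCNT arrays too, SSLP1 at 12.43 to 12.78 and KRT19 at 12.04 to 12.36. The intermediate filament gene VIM was at least 546-fold, the collagen gene COL1A2 at least 357-fold, S100A4 at least 358-fold and the protease gene CTSK at least 310-fold lower in each kind of conceptus than in fibroblasts. FMOD was at least 198-fold lower in AI and IVP conceptuses, and it stood at the lowest value of 2.42 on each SCNT array too. KLF4, a pluripotency factor also made in other cells, was at least 30.7-fold lower in all 3, while CRIPTO was at least 3.30-fold and 2.66-fold higher in IVP and SCNT conceptuses. CRIPTO also passed as higher in AI than in FB, with every array of both groups below log2 4. That call ended without AI 3 or FB 3. Of 8164 probe sets tested over all arrays, 6302 differed between AI and FB (3396 higher), 6424 between IVP and FB (3512 higher) and 6519 between SCNT and FB (3676 higher), with median differences of all probe sets of 0.11, 0.14 and 0.20.

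Genes of interest for conceptus development were given whether or not they changed. IFNT2, of the family that signals pregnancy to the uterus, stood at 13.25 ± 0.16, 13.29 ± 0.10 and 13.26 ± 0.06 log2 units in AI, IVP and SCNT conceptuses and at 2.68 ± 0.05 in fibroblasts (n = 3 each). The brightest probe set of PTGS2, an enzyme of prostaglandin synthesis, read 11.18 ± 0.34, 11.54 ± 0.05 and 11.65 ± 0.31, while its second probe set read 7.12 ± 1.14, 7.84 ± 0.25 and 6.22 ± 0.45, lowest instead of highest in SCNT, and the remaining one lay below log2 4 on every array. IGF2R, a maternally expressed imprinted gene, read 5.70 ± 0.36, 6.72 ± 0.22 and 6.81 ± 0.08 and 8.02 ± 0.10 in fibroblasts. COL1A1 was above log2 4 in fibroblasts (8.93 ± 0.20) and in no conceptus array. POU5F1, IGF2 and DNMT1 lay below log2 4 on every array. XIST, the RNA of the inactive X chromosome, read 4.08 ± 1.31 on the AI arrays and 4.33 ± 2.08 on the IVP arrays, where it ranged from 2.42 to 6.55, and 2.42 on each SCNT and FB array.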

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

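The covariate, array-pair, contamination and heat shock tests of this part were chosen after the results were seen, while the counts of other splits had been decided beforehand.

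On 1 probe set each, VCAN and DNAJB1 stood below every AI array in SCNT conceptuses and above every AI array in IVP conceptuses, though neither fall of SCNT from AI passed there (adjusted p = 0.0893 and 0.124). On the other probe set of VCAN the fall of SCNT passed (at least 1.38-fold, adjusted p = 0.0430) and the rise of IVP did not (adjusted p = 0.135). The brighter probe set of DNAJB1 did not show this, with SCNT 1 at 7.82 above all AI arrays. The difference itself, tested with limma as SCNT minus IVP, was -1.30 for VCAN (adjusted p = 0.0337) and -1.40 for DNAJB1 (adjusted p = 0.0236), on 3 arrays each. The calls ended without SCNT 1, SCNT 2, SCNT 3 or IVP 2, that of VCAN also without IVP 3 and that of DNAJB1 without IVP 1. Over the omission of each array, kept calls included, the log2 difference lay between -1.56 and -1.10 for VCAN and between -1.65 and -1.22 for DNAJB1. Signals in the control probe sets drew attention too. The gap between the 3' and 5' probe sets of GAPDH was 0.45 on SCNT 2, 0.51 on IVP 2 and 0.89 on IVP 3, above the highest AI value of 0.38. Hybridization spikes read 8.94 on IVP 2, where the highest AI array read 8.91, and poly-A spikes read 6.44 on IVP 2, where the highest AI array read 6.03. Both spike signals were lower on every SCNT than on every IVP array, so array signal stays open for the differences between SCNT and IVP. ADD3 and ATP1B1 passed with the spike covariate, which cannot settle it for them, since the 2 groups do not overlap in spike signal. The sex mix stays open for these differences too. XIST read 2.42 on each SCNT array and on IVP 2, but 6.55 on IVP 3. With the XIST covariate 7 probe sets passed in place of 40, though the 40 differences kept a median 0.933 of their size. The 6 list calls in SCNT against AI ended with that covariate, so the sex mix stays open for them as well. Groups of 3 arrays were not tested for outliers.

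The AI arrays stood apart from both the IVP and the SCNT arrays, with 995 probe sets changed the same way. Array signal as the spikes measure it is argued against as the whole cause. RNA integrity as the GAPDH gap measures it and the sex mix as seen through XIST overlap between the groups. That overlap is all that speaks against them as the whole cause. An AI array correlated over the 6892 probe sets of the conceptus fit at 0.971 or above with the other AI arrays, but at most at 0.957, 0.941 and 0.941 with IVP or SCNT arrays that lay closer to it in spike signal (16 pairs), GAPDH gap (11 pairs) and XIST (9 pairs). With each measure in the model the smaller median ratio of the change to that without it was 0.995, 1.0001 and 0.992, with 735, 427 and 837 of the 995 still called. The spike level, GAPDH gap and XIST themselves reached an unadjusted p under 0.05 in limma for 882, 403 and 465 probe sets. Chance gives 345, and after adjustment 0, 0 and 1 passed. The 2 ratios of the GAPDH gap and XIST therefore decide nothing. The array pairs add little for them. Over the probe sets tested on all arrays, every AI pair correlated above every pair of an AI with an IVP or SCNT array. Any measure that overlaps between the groups would thus give the same outcome. RNA integrity and sex stay open beyond what these measures capture. An effect of embryo production outside the animal stays open, as untested. The labels used here do not tell whether the AI arrays were hybridized on another date, so a difference in processing stays open too.

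ITGB2, RAC2 and CD48, known from leukocytes, were higher on the AI arrays. Maternal blood or immune cells are argued against, since 2 of 25 list genes lay above log2 4 on any AI array (ALAS2 at 7.86 and GZMB at 6.60), with HBB at 2.44 and PTPRC at 2.42. Uterine epithelium is argued against in the same way, with 2 of 13 genes above log2 4 (CST6 at 5.01 and MSX1 at 4.67) and PAEP at 2.56. No blood or uterine sample was measured, so both arguments hold only as far as the silent probe sets can detect their transcripts. Outside the AI arrays, CD3G, LAPTM5 and GZMB reached 6.32, 6.07 and 5.98. Expression by the conceptus itself may be the source, and it was not tested.

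Heat shock genes were higher in IVP than in AI conceptuses by a median of 0.41 over all genes. The low RNA integrity of IVP 3 alone is argued against, since the shift was 0.40 without that array (adjusted p = 0.0242). RNA integrity across the IVP arrays stays open, as the GAPDH gap of IVP 2 (0.51) was also above the highest AI value of 0.38. With that gap as a covariate the shift was 0.33 (camera, adjusted p = 0.0395). This cannot settle it, since the gap itself reached an unadjusted p under 0.05 in limma for 403 probe sets, where chance gives 345. Array signal is argued against as the whole cause. The spike level itself reached an unadjusted p under 0.05 in limma for 882 probe sets, against 345 expected by chance, and passed for 0 after adjustment. With the spike level in the model the shift was 0.49 (adjusted p = 0.00384). Without the 3 arrays of high spike-in signal, which leaves 1 IVP array, it was 0.32 and missed the threshold (adjusted p = 0.0627), and over all settings adjusted p ranged from 0.00288 to 0.713. Handling before extraction may differ between groups and was not tested.

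Other splits of the same arrays were counted for each result. The 10 splits of 6 arrays are too few for a share under 0.05. The real split called 1902 probe sets in SCNT against AI and the highest other split 0, and 1234 against 0 in IVP against AI, 40 against 3 in SCNT against IVP, 6302 against 0 in AI against FB, 6424 against 0 in IVP against FB and 6519 against 0 in SCNT against FB, so that 1 split reached the real value in each. For gene lists the real and the highest other counts were 6 and 9 in SCNT against AI (3 splits with as many), 2 and 6 in IVP against AI (5 splits) and 2 and 6 in SCNT against IVP (8 splits). For the fibroblast-high probe sets the sizes were 0.25 and 0.12 in SCNT against AI and 0.07 and 0.05 in SCNT against IVP (1 split each), and for the fibroblast-low probe sets 0.06 and 0.10, and 0.04 and 0.07 (3 splits each). Of 100 splits of the 9 conceptus arrays into 3 groups, the real one included, 1 shared as many as the 995 probe sets. Of the other splits, 2 kept the AI arrays together and gave up to 952, while those that parted them gave at most 7. A split that parts the AI arrays puts their distance from the others into the spread within groups. The low counts therefore show only that the AI arrays stand together, and they exclude nothing further.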

How the results depend on the processing

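Every setting chosen beforehand was run, and the covariates, the omission of the 3 arrays of high spike-in signal and the list chosen before the conceptus filter were added after the data had been seen. No direction of a called result turned. Of the named genes called, 52 of 104 in SCNT against AI, 27 of 84 in IVP against AI and 2 of 19 in SCNT against IVP (ADD3 and ATP1B1) passed in every setting, and 15, 16 and 16 of 16 each in AI, IVP and SCNT against FB. Leaving out 1 array at a time kept 78, 55, 4, 15, 16 and 16 in that order. All 10 list calls were lost in at least 1 setting.

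Without the filter 984 probe sets changed in SCNT against AI, 484 in IVP against AI, 7 in SCNT against IVP and 401 in both against AI. With the filter at log2 6, fewer were tested, and the counts were 1006, 681 and 22, and 3127, 3212 and 3234 for AI, IVP and SCNT against FB. Requiring 2-fold as well gave 485 and 371 against AI and 3775, 3837 and 3957 against FB, or 505, 397, 83 (SCNT against IVP), 3776, 3840 and 3957 with unadjusted p. SCNT against IVP gave 136 with all 12 arrays in the fit, 107 with array weights, 2 with the spike, 8 with the GAPDH and 7 with the XIST covariate and 5 without the high-spike arrays, where IVP against AI gave 580 and the shared count was 532. IVP against AI gave 502 with the GAPDH covariate. The causes were not tested beyond the number of probe sets.

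Replicate numbers did not pair the arrays: the correlation of deviations ran from -0.147 to 0.213 for same-numbered pairs (18 pairs, 3 above 0.1) and from -0.195 to 0.177 for others. With the replicate block 1733 probe sets changed in SCNT against AI, 1072 in IVP against AI, 23 in SCNT against IVP and 871 in both, and 6248, 6399 and 6465 against FB.

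List calls in IVP against AI numbered 0 with the filter at log2 6, 1 with quantile normalization, 5 with the GAPDH covariate, 0 with an estimated correlation and 4 with the mean of a gene's probe sets. In SCNT against AI they numbered 0 with the filter at log2 6, 0 with an estimated correlation, 0 with the spike or the XIST covariate and 0 without the high-spike arrays, and in SCNT against IVP 0 with an estimated correlation, 1 with the spike covariate and 1 without the high-spike arrays. Drawn against the same control group, the fibroblast-high shift in SCNT against AI was -0.0020 (p = 0.812) and the fibroblast-low shift -0.41 (p = 5.74e-12), and the fibroblast-low shift in SCNT against IVP was -0.043 with an estimated correlation (p = 0.0780).

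Leaving out 1 array gave 1190 to 1690 changes in SCNT against AI, 794 to 1163 in IVP against AI, 9 to 33 in SCNT against IVP, 672 to 940 in both, and 5968 to 6287, 6122 to 6281 and 6222 to 6344 against FB. List calls ran from 0 to 7, 1 to 4 and 2 to 6 in the 3 conceptus comparisons. Fibroblast-high shifts ran from -0.27 to -0.21 in SCNT against AI and from -0.08 to -0.06 in SCNT against IVP, fibroblast-low shifts from -0.09 to -0.01 and from -0.061 to -0.020.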

Other observations

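The division of the changed probe sets by the group that departed from AI was chosen after the results were seen. Among the genes lower in SCNT than in IVP conceptuses were 4 of plasma proteins, picked after their values were seen and not tested as a list. AHSG was 11.1-fold lower in SCNT than in IVP conceptuses (adjusted p = 0.0160, n = 3 each), with log2 differences from AI of -4.70 in SCNT and -1.22 in IVP, and FETUB, a related fetuin gene, differed from AI by -1.61 and -0.04. APOH, of lipoproteins, differed from AI by -2.06 and 0.16, and PROS1, of the coagulation cofactor protein S, by -1.42 and -0.04. The direct SCNT minus IVP differences were -2.22 for APOH (adjusted p = 0.0337), -1.57 for FETUB (adjusted p = 0.0380) and -1.37 for PROS1 (adjusted p = 0.0403). The AHSG call ended without SCNT 2, IVP 2 or IVP 3, and those of APOH, FETUB and PROS1 did too. The APOH call also ended without SCNT 1 or IVP 1, and that of FETUB without SCNT 3 or IVP 1. The PROS1 call also ended without SCNT 1 or SCNT 3. Over the omission of each array, kept calls included, the log2 differences of AHSG ran from -4.14 to -2.97. Those of APOH, FETUB and PROS1 ran from -2.58 to -1.89, -1.74 to -1.41 and -1.52 to -1.22. Of the 5 AHSG probe sets, 4 passed, with differences between SCNT and IVP of -3.48 to -2.73, and the fifth differed by -0.21, so whether some bind related transcripts stays open.

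ADD3 and ATP1B1 shared this pattern, with log2 differences from AI of -2.67 and -1.83 in SCNT and 0.03 and 0.51 in IVP conceptuses. BMP7 instead rose in IVP conceptuses, by 1.01, with -0.01 in SCNT, and ZFAND2A lay above log2 4 in IVP conceptuses and below it in the others. Of the 40 probe sets that differed between SCNT and IVP, 26 passed against AI in SCNT alone (14 lower and 12 higher than in IVP), 13 in IVP alone (10 lower in SCNT and 3 higher) and 1, of PLET1, in both.

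Of the 32 gene lists, 8 had too few measured genes for a test. The numbers above the filter were 1 of 7 genes on the array for epiblast and pluripotency, 0 of 6 for gastrulation and mesoderm, 1 of 13 for uterine epithelium, 2 of 25 for blood and immune cells, 1 of 33 for interferon-stimulated genes, 2 of 17 for the IGF axis, 4 of 16 for retinoids and 1 of 3 for X inactivation and Y-linked genes. The array annotation pairs no probe set with IFNT, CDX2 or H19.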
